A study of Homo sapiens with 18 samples.

How the data were processed

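Gene expression was measured in HEK293 cells, an established human embryonic kidney line, on 18 Affymetrix HG-U133A arrays. Each array carries 22283 probe sets, of which 68 are controls. The labels put the arrays in 6 groups of 3: unstored monolayers, unstored spheroids, spheroids after 2 weeks of dry storage, and stored spheroids 6, 24 and 72 h after medium was added back. Groups and replicate numbers were taken from the sample titles. The labels describe all conditions as done in triplicate but do not say that the replicates were separate cultures, so the p-values measure the spread between these samples only, and part of that spread may be technical.

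The deposited table holds 1 intensity per probe set and array, in whole numbers on a linear scale. The summary method, the scaling and the background step are not given in the sources used here. The values themselves show some of it: the lowest value on any array lay between 163 and 173, so no background had been subtracted down to 0, and each array stopped at its own ceiling between 44004 and 45182. Between 74 and 235 probe sets per array lay at 99% of that ceiling or above, 62 of them on every array. Fold changes are therefore compressed at both ends of the scale. Dim probe sets keep a background that was not removed, and bright ones cannot rise further. The files that accompany the arrays hold the settings of the hybridisation and scan, per the file headers; only the hybridisation day and time were read from them, and are given here as codes. The number of arrays per group limits the precision of every value.

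The arrays' 2% trimmed means lay between 2577 and 2875, a ratio of 1.116, which was too large for the deposited scaling to be left as it was under the rule set for it. Values were therefore transformed to log2 and quantile normalised, and then floored at the 10th percentile of all values, a signal of 395. Control probe sets were left out of the tests. A probe set was kept if its signal lay above the array median on at least 3 of the 18 arrays, which left 12709. Gene symbols came from the platform annotation supplied with the data: 19071 probe sets had 1 symbol, 1043 had several and 2169 had none, and no symbol needed an update. Probe sets with several symbols or none were tested but not named. No genome was used, so no coordinates are given. Of the kept probe sets 11270 had 1 symbol and stood for 7861 genes, and a gene was represented by its probe set with the highest mean over all arrays.

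Each comparison was a contrast in 1 linear model of the 6 group means over all 18 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes with an intensity trend, two-sided). P-values were adjusted with the Benjamini-Hochberg method over the 12709 probe sets of a comparison, and a probe set was called changed at an adjusted p under 0.05. A moderated F test over the same model asked for any difference among the 6 groups. Mean signals are given as mean ± SD of the normalised signal on the linear scale, and fold changes as ratios of the geometric means. Where all 3 arrays of the brighter group lay at the ceiling, a fold is given as a lower bound. Of the kept probe sets 209 lay at the ceiling on every array of at least 1 group, and 22 lay at the floor in the same way.

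Gene lists were fixed in advance from textbook knowledge: 35 lists with 957 genes, of which 824 were on the array and 670 were measured. The 33 lists with at least 5 measured members were tested with camera, which asks whether a list's members moved differently from the other probe sets, with a preset correlation of 0.01 between members and Benjamini-Hochberg adjustment over the lists of a comparison. Camera was also run with the correlation estimated from the residuals. Members were counted as rising or falling by the test over all probe sets, and again adjusted over the list alone. Named genes were those with the largest rise and fall among called probe sets with 1 symbol, no overlap between the arrays of the groups compared, and a higher group mean above the median of all values kept. The rule took 10 genes each way in 4 comparisons and 5 each way in 24 h and 72 h recovery against stored 0 h. From each list up to 4 members of lowest p were also named, with members that moved against the list. Samples, comparisons, their tests, the lists, the rule for named genes and part of the alternatives were fixed before the data were examined, and what was added later is named below.

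The linear model was tested on simulated data with 12709 probe sets, of which 100 changed by log2 0.5 and 100 by log2 1 in each comparison. The share of changes of log2 1 that was recovered was 99% for spheroid against monolayer, 99% for stored 0 h against spheroid, 96% for 6 h and 99% for 24 h against stored 0 h, and 100% for both comparisons of 72 h. For log2 0.5 the shares were 68%, 74%, 68%, 67%, 79% and 81% in the order of the comparisons in the report. Between 6 and 11 unchanged probe sets were called in each. The simulated values had independent noise, few changed probe sets and no day or session effect, and were not normalised. These shares and counts therefore describe the model alone and not the errors of the real comparisons.

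The arrays were hybridised on several days, coded 1 to 5. Day 1 held the monolayers and day 2 the spheroids. Day 3 held all stored 0 h and 6 h arrays and 24 h replicate 2, day 4 held 24 h replicate 1, and day 5 held 24 h replicate 3 and the 72 h arrays. The monolayer and spheroid groups each lay on a day of their own, so for every comparison that involves them the day and the group cannot be told apart by a block. The day entered as a block for the comparisons among stored and recovering spheroids, and as a random block elsewhere. Arrays started within 30 minutes of each other were taken as a session, and the session was a further block for 6 h against stored 0 h, in a fit of the arrays of that day and in a fit of all 18.

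The alternatives fixed in advance were median centring of the log2 values, other floors and filters on dim probe sets, a fit without the intensity trend, array weights, a minimum change of 2-fold, a fit of the compared arrays alone, the day as a block, the replicate number as a block, and leaving out each array in turn. Values as deposited, scaling to the bacterial spike-in controls, leaving out probe sets at the ceiling, the session blocks and the tests of gene families were added after the data were seen. Figures were drawn with matplotlib 3.10.9.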

Results

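HEK293 cells, a human line derived from embryonic kidney and transformed with adenoviral genes, were grown as spheroids over agarose for 4 days. The medium was taken off, and the spheroids were kept dry in vacuum-sealed flasks at room temperature in the dark for 2 weeks before medium with 10% serum was added back. RNA was profiled on 18 arrays, 3 in each of 6 groups: monolayers at 60 to 70% confluence, unstored spheroids, stored spheroids at 0 h, and spheroids 6, 24 and 72 h after rehydration. Median signals per array lay between 1300 and 1401. Correlations between arrays are across probe sets, which are not independent replicates. Within a group the mean r was between 0.982 and 0.995. Between groups it was 0.964 for monolayer and spheroid, 0.8 for spheroid and stored 0 h, and 0.953 for spheroid and 72 h recovery. Along the principal component that held 70.6% of the variance, the monolayer and spheroid arrays lay between -44.6 and -43, the stored and 6 h arrays between 42.4 and 45.9, the 24 h arrays between 19 and 20, and the 72 h arrays between -20.7 and -19.3. Of 12709 probe sets, 11528 (90.71%) differed among the 6 groups by the moderated F test of limma.

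**Figure D1:**
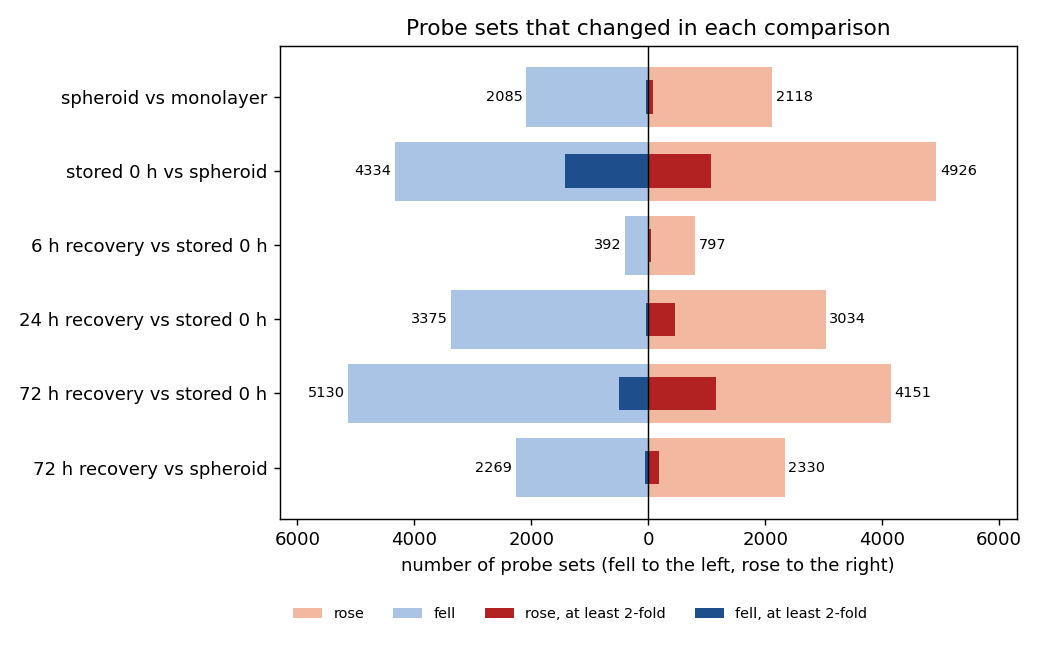
Number of probe sets called changed by limma in each comparison (x axis, count; fell to the left, rose to the right), with those of at least 2-fold as dark inner bars. Stored 0 h against spheroid gave 4926 rises and 4334 falls, while 6 h against stored 0 h gave 797 and 392.

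Growth as spheroids, before any storage, was set against growth as a monolayer. IER3, an early response gene that modulates apoptosis, was 4.93-fold higher in spheroids (10328 ± 1012 against 2091 ± 141, SD, n = 3). BHLHE40, a transcriptional repressor, rose 4.21-fold, SAT1, which acetylates polyamines, rose 3.64-fold, and HILPDA, a lipid droplet protein induced by low oxygen, rose 3.1-fold. SERPINF1, GADD45A, ADAMTS1, CGA, DDIT4 and CDKN1A rose by 2.85-fold to 3.06-fold. The receptor phosphatase gene PTPRO was 4.7-fold lower (3391 ± 1923 against 14399 ± 2618). The translation factor genes EIF5A and EIF2S3 were 3.25-fold and 3.01-fold lower, and TMEM259, ATP6V0D1, STT3A, FARSA, PCDH7, VARS1 and PPIB were lower by 2.07-fold to 3.5-fold. In all, 2118 probe sets rose and 2085 fell, 126 of them by at least 2-fold.

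Genes of the hypoxia response rose together in spheroids. Of 26 measured members 20 rose and none fell (21 and 0 adjusted over the list alone), with a median log2 change of 0.66 (camera adjusted p = 1.35e-11, adjusted p = 0.0631 with an estimated correlation). KDM3A, a histone demethylase, rose by log2 1.04 ± 0.07 (SE), and MXI1, an antagonist of MYC, by 0.72 ± 0.06. Of 16 p53 target genes 11 rose and none fell (11 and 0 adjusted over the list alone; median 0.39, adjusted p = 3.41e-05, and adjusted p = 0.00873 with an estimated correlation). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose by 1.51 ± 0.11, the death receptor gene TNFRSF10B by 0.45 ± 0.06 and the DNA repair gene DDB2 by 0.41 ± 0.06. Genes of ribosome assembly were lower, with 17 of 30 falling and 2 rising by both adjustments, over all genes and adjusted over the list alone (median -0.23, and -0.12 with spike-in scaling; adjusted p = 0.000133, adjusted p = 0.152 with an estimated correlation). RRP9 fell by 0.57 and NOP16 by 0.66, while POLR1B rose by 0.33 and DDX21 by 0.20.

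Of 27 immediate early genes, which respond within minutes to growth factors and stress, 14 rose in spheroids and 1 fell, also adjusted over the list alone (median 0.32, adjusted p = 0.000228, adjusted p = 0.435 with an estimated correlation). IER5 rose by 1.15 and DUSP1 by 1.06, while MYC fell by 0.67. Of 30 targets of the amino acid response factor ATF4, 15 rose and 4 fell (15 and 5 adjusted over the list alone; adjusted p = 0.0084, adjusted p = 0.308 with an estimated correlation). The asparagine synthetase gene ASNS rose by 1.07, and the amino acid transporter genes SLC3A2 and SLC7A5 fell by 0.54 and 0.33. Matrix and integrin genes rose in 10 of 26 cases with no fall (12 and 0 adjusted over the list alone; adjusted p = 0.0084, adjusted p = 0.281 with an estimated correlation), among them TIMP1 by 1.09 and fibronectin, FN1, by 0.79. FOXO targets rose in 9 of 17 cases with no fall, also adjusted over the list alone (adjusted p = 0.00938, adjusted p = 0.281 with an estimated correlation), with YPEL5 at 0.72 and CITED2 at 1.06. Genes of the unfolded protein response rose in 8 of 17 cases and fell in 2, also adjusted over the list alone (adjusted p = 0.0203, adjusted p = 0.152 with an estimated correlation). The chaperone genes DNAJB9 and HSPA5 rose by 1.12 and 0.51, and CALR and HYOU1 fell by 0.51 and 0.39. The other 25 lists were not called. Monolayer and spheroid arrays were hybridised on a day each, so day and group cannot be told apart. Rises made up 50.4% of the calls, against 60.5% with median centring and 77.8% of 1861 calls with arrays scaled to their spike-in controls.

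Storage was followed by the widest difference from the unstored spheroids among the 3 comparisons that involve unstored cells. ZNF34, a zinc finger gene, was 14.9-fold higher in stored spheroids at 0 h than before storage (16074 ± 1827 against 1075 ± 43, n = 3), and CCNL1, a cyclin that acts in splicing, was 13.5-fold higher (32787 ± 1372 against 2437 ± 144). FOS, a subunit of the AP-1 transcription factor, rose 10.1-fold, GPR50 11.8-fold, and the stress gene GADD45B 8.42-fold, with 1 of its 3 stored arrays at the ceiling. CDKN2AIP, PCF11, NUFIP1, CCN1 and the splicing kinase gene CLK1 rose by 7.48-fold to 9.57-fold. IGFBP5, which binds insulin-like growth factors, was 14.8-fold lower (962 ± 90 against 14608 ± 3961). The neurofilament gene NEFM was 13.7-fold lower and SLIT2, which encodes a guidance ligand, 13.2-fold lower. NDUFAF3, VCAN, HMGA2, ADD3, PTPRK, COCH and ROBO1, a receptor for SLIT proteins, were 8.42-fold to 9.67-fold lower. Of the 12709 probe sets 4926 rose and 4334 fell. Of these, 1066 rose and 1424 fell by at least 2-fold (450 and 2567 with spike-in scaling). On 70.65% of probe sets the arrays of the 2 groups did not overlap, where chance gives 10%.

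Immediate early genes were higher in stored spheroids. Of 27 measured, 24 rose and none fell (25 and 1 adjusted over the list alone; median 1.05, and 0.60 with spike-in scaling; adjusted p = 1.57e-06, adjusted p = 0.285 with an estimated correlation). FOSB rose by log2 2.51 ± 0.15 (SE), and IER2 rose by at least 2.01 because all 3 stored arrays lay at the ceiling. Of 17 genes of NF-kB and cytokines 14 rose and none fell, also adjusted over the list alone (median 0.51, and 0.08 with spike-in scaling; adjusted p = 0.00373, adjusted p = 0.279 with an estimated correlation). The chemokine genes CXCL8 and CXCL2 rose by 2.64 ± 0.22 and 2.29 ± 0.20, TNFAIP3, an inhibitor of NF-kB signalling, by 2.13 ± 0.17, and NFKB1 by 1.05 ± 0.09. Markers of leukocytes, which the culture should not hold, rose in 6 of 8 cases with none falling (median 0.40, camera adjusted p = 0.189), with CD14 at 0.76 and LAPTM5 at 0.45. Spike-in scaling, which moved the median of all probe sets from 0.06 to -0.35, took away the call of LAPTM5.

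Genes of energy metabolism were lower in stored spheroids. Of 16 glycolysis genes 13 fell and none rose, also adjusted over the list alone (median -0.92, adjusted p = 6.85e-05, adjusted p = 0.103 with an estimated correlation). The phosphofructokinase genes PFKP and PFKM fell by log2 2.34 ± 0.09 and 1.45 ± 0.06, and GPI, glucose-6-phosphate isomerase, fell by 2.18 ± 0.09. Of 58 genes of oxidative phosphorylation 40 fell and 7 rose, also adjusted over the list alone (median -0.47, adjusted p = 1.87e-05, adjusted p = 0.288 with an estimated correlation). With spike-in scaling the median of these genes was -0.795. Cytochrome c, CYCS, fell by 1.27 and ATP5PD by 2.17, while NDUFS3 rose by 1.02. Lipid genes fell too. Cholesterol synthesis had 12 of 17 genes falling and 1 rising, also adjusted over the list alone (median -0.93, adjusted p = 0.00246, adjusted p = 0.236 with an estimated correlation). INSIG1, a sterol sensor, fell by 2.71, and FDPS, which makes farnesyl diphosphate, by 1.80, while EBP rose by 0.42. Fatty acid synthesis had 9 of 11 falling and 1 rising, also adjusted over the list alone (median -0.99, adjusted p = 0.00373, adjusted p = 0.103 with an estimated correlation), with SCD, the stearoyl-CoA desaturase, down by 2.78 and ACSL1 up by 0.56. Matrix and integrin genes fell in 16 of 26 cases and rose in 2, also adjusted over the list alone (median -0.58, adjusted p = 0.00749, adjusted p = 0.285 with an estimated correlation). With spike-in scaling the median of the matrix and integrin genes was -1.02. The basement membrane genes COL4A2 and LAMC1 fell by 1.55 and 2.10, while CD44, a hyaluronan receptor, rose by 1.45.

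Some lists with many calls missed the threshold of camera, in a comparison where 38.1% of all measured genes rose and 34.9% fell. Mitosis genes rose in 22 of 40 cases and fell in 6, also adjusted over the list alone (adjusted p = 0.0604; median 0.22, but -0.11 with spike-in scaling), with BIRC5 at log2 1.59. Hypoxia genes fell in 16 of 26 cases and rose in 5 by both adjustments, over all genes and adjusted over the list alone (adjusted p = 0.0653), with HILPDA at -2.27. In all, 26 lists were not called.

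The 28S ribosomal RNA control at its 3' end, which no test used, read 5247 ± 2361 in stored spheroids and 2420 ± 241 in unstored ones, 2.03-fold apart (n = 3). Another control for the 3' end of 28S read 3002 ± 516 and 2389 ± 235. The GAPDH and ACTB controls for RNA length lay at the ceiling, so their 3' to 5' log2 ratios, 0.002 and -0.032 higher in stored spheroids, say nothing on RNA length (exact permutation p = 0.1, the smallest that 3 against 3 arrays can give, and 0.8, two-sided). The spheroid arrays had a hybridisation day of their own. Scaling to the spike-in controls moved the median log2 change of all probe sets from 0.06 to -0.35 and the share of rises from 53.2% to 20.8%, so rises and falls here are relative to the bulk of the probe sets. This scaling used the bioB, bioC and bioD controls and left out the cre controls. In normalised values the cre controls read log2 14.522 and 14.853 in spheroids and 14.615 and 14.842 in stored ones. The controls used all had higher means after storage, from 13.757 to 13.953 for bioD 3' and from 9.674 to 10.102 for bioB middle. The size of the shift thus depends on the controls chosen. The amount of RNA per cell was not measured, so the shift is no evidence of a general loss of RNA.

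**Figure D2:**
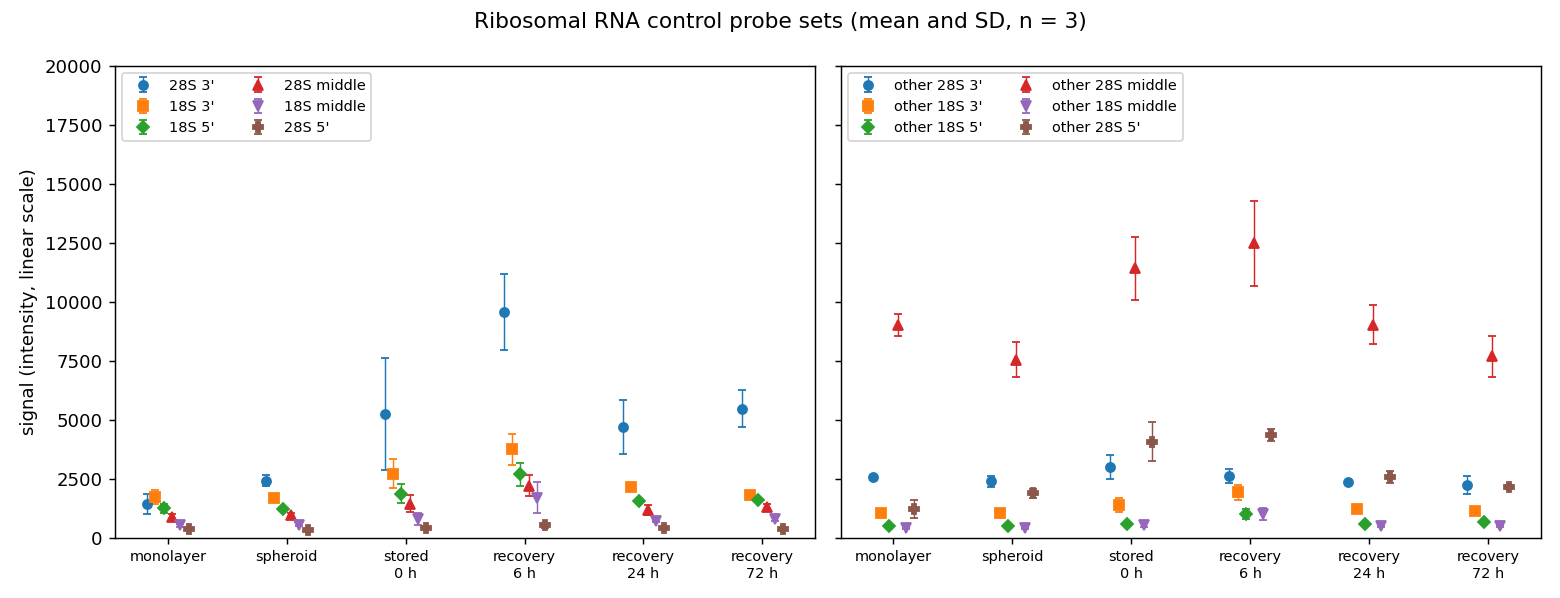
Signal of 12 control probe sets for 18S and 28S ribosomal RNA (y axis, normalised intensity on a linear scale) in each group, as mean and SD of 3 arrays, with the array's newer controls on the left and its other controls on the right. The 28S 3' control read 2420 in spheroids, 5247 at 0 h and 9571 at 6 h, and the other 28S 3' control 2389, 3002 and 2627.

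The early hours after rehydration were examined by setting 6 h against stored 0 h. BCL6, a transcriptional repressor, was 3.83-fold higher at 6 h (3602 ± 151 against 943 ± 109, n = 3). SLC5A3, the inositol transporter that responds to osmotic stress, was 3.45-fold higher (3828 ± 277 against 1109 ± 86), and HOMER1, a synaptic scaffold gene, 2.78-fold higher. PREPL rose 2.25-fold. These 4 genes kept their calls when the hybridisation session was a block in a fit of the 7 arrays of the stored arrays' day (adjusted p = 0.0317 for each), with log2 changes of 1.96 for BCL6, 1.87 for SLC5A3, 1.32 for HOMER1 and 1.28 for PREPL. The other 16 named genes lost theirs in that fit, which left 3 residual degrees of freedom: CDK13, PPP1R10, CLDND1, EIF5A, KHDC4 and PLAGL1, 2.13-fold to 2.54-fold higher, and CCN1, CEBPA, MUC5AC, DEGS1, CDCA4, KAT7, ZNF614, SNX19, YWHAE and MLPH, 1.37-fold to 1.57-fold lower. All 16 had the same sign with the block, and for 6 of them the log2 change stayed within 10%, for 1 it was larger and for 9 smaller. PPP1R10 went from 1.32 to 1.59 and KHDC4 from 1.12 to 1.15, while PLAGL1 went from 1.09 to 0.40. With the same block in a fit of all 18 arrays, which left 8, PPP1R10, CLDND1, KHDC4, DEGS1, CDCA4 and MLPH kept their calls too, and 10 genes lost theirs. In all, 797 probe sets rose and 392 fell, with 50 rising and none falling by at least 2-fold.

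Heat shock genes rose in 8 of 18 cases at 6 h and none fell (9 and 0 adjusted over the list alone; median 0.15, and 0.17 with the session as a block; adjusted p = 0.000455, adjusted p = 0.356 with an estimated correlation). The co-chaperone gene DNAJB6 rose by log2 1.23 ± 0.15 (SE) and DNAJB1 by 0.39 ± 0.09. Oxidative phosphorylation had 5 of 58 genes rising and none falling, also adjusted over the list alone (median 0.12, but 0.04 with the session as a block; adjusted p = 3.49e-05, adjusted p = 0.665 with an estimated correlation), among them COX7C by 0.39 and CYCS by 0.40. Of the immediate early genes 3 of 27 rose and none fell, also adjusted over the list alone (adjusted p = 0.177), with EGR3 at 1.66 ± 0.19. Of 19 oxidative stress genes 3 rose (4 rose and 1 fell adjusted over the list alone; adjusted p = 0.291), with the heme oxygenase gene HMOX1 at 0.96 ± 0.12 and its regulator NFE2L2 at 0.94 ± 0.15. The other 31 lists were not called. The 28S 3' ribosomal RNA control read 9571 ± 1624 at 6 h and 5247 ± 2361 at 0 h, and the other 28S 3' control 2627 ± 292 and 3002 ± 516. All stored and 6 h arrays shared a hybridisation day, but stored replicates 1 and 2 were run in an earlier session than stored replicate 3 and the 6 h arrays. With the session as a block 200 probe sets were called over all arrays and 14 over the arrays of the day, where 179 were called without the block. With only the 6 arrays compared there were 180, with spike-in scaling 346, and without stored replicate 2, stored replicate 3, 6 h replicate 2 or 6 h replicate 3 there were 695, 2305, 755 and 598. Rises made up 67% of the calls, against 91.3% with median centring, 79.4% as deposited and 93.9% with spike-in scaling.

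At 24 h the difference from stored 0 h had widened to 3034 rising and 3375 falling probe sets, with 460 and 46 of at least 2-fold. MSANTD2 was 7.71-fold higher than at 0 h (3629 ± 329 against 470 ± 27, n = 3), PREPL 6.26-fold, ATP6V1C1, a subunit of the proton pump of lysosomes, 5.65-fold, DNAJB6 5.51-fold and PSPC1, a paraspeckle protein gene, 5.09-fold. CDCA4 was 2.64-fold lower (6528 ± 547 against 17233 ± 800), and TRMT61B, RBM12, FZD6 and CYP27B1, the enzyme that activates vitamin D, were 2.25-fold to 2.27-fold lower.

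Mitosis genes fell at 24 h, with 31 of 40 falling and none rising (0 rose and 32 fell adjusted over the list alone). Their median log2 change was -0.51, or -0.48 with the hybridisation day as a block (adjusted p = 1.67e-10, adjusted p = 0.0426 with an estimated correlation). CDKN3, a phosphatase that acts on cyclin-dependent kinases, fell by 1.08 ± 0.09 (SE), BIRC5, survivin, by 0.70 ± 0.04 and CENPA, the histone variant of centromeres, by 0.81 ± 0.07. Heat shock genes rose in 12 of 18 cases and fell in 2 (13 and 2 adjusted over the list alone; median 0.43, and 0.39 with the day as a block; adjusted p = 0.00087, adjusted p = 0.145 with an estimated correlation), with DNAJB1 up by 0.84 and HSPA9 down by 0.37. Autophagy and lysosome genes rose in 15 of 29 cases and fell in 4 (16 and 5 adjusted over the list alone; median 0.24, and 0.20 with the day as a block; adjusted p = 0.0274, adjusted p = 0.101 with an estimated correlation). The lysosomal enzyme genes CTSA and NEU1 rose by 1.02 and 0.97, while GABARAPL1 fell by 0.98. Oxidative phosphorylation had 22 of 58 genes rising and 5 falling, also adjusted over the list alone (median 0.11, and 0.13 with the day as a block; adjusted p = 0.00578, adjusted p = 0.789 with an estimated correlation), with CYCS up by 1.14 and NDUFA7 down by 0.66. With spike-in scaling the median of the oxidative phosphorylation genes was 0.22. The other 29 lists were not called. The 24 h arrays came from 3 days: with the day as a block 3306 probe sets were called, and the 1 array at 24 h from the stored arrays' day, assumed to vary like the other groups, gave 3593 against the 3 stored arrays. Rises were 47.3% of the calls, against 60% with median centring and 80.5% of 3504 calls with spike-in scaling.

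At 72 h, 4151 probe sets were higher and 5130 lower than at 0 h, 1154 and 500 of them by at least 2-fold. ACTA2, smooth muscle actin, was 8.79-fold higher (15980 ± 258 against 1819 ± 37, n = 3), FGF13 8.15-fold, TP53I3, a p53 target, 7.62-fold, ID3, an inhibitor of differentiation factors, 7.18-fold and SLIT2 7.14-fold. ZNF34 was 5.85-fold lower (2747 ± 322 against 16074 ± 1827), MXD1, a partner of MAX, 5.31-fold, CYP27B1 4.96-fold, CXCL8 4.14-fold and GPR50 4.09-fold lower.

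Oxidative phosphorylation genes were higher at 72 h than at 0 h, with 41 of 58 rising and 3 falling (42 and 4 adjusted over the list alone; median 0.38, and 0.41 with the day as a block; adjusted p = 2.39e-07, adjusted p = 0.236 with an estimated correlation). CYCS rose by log2 1.26, UQCRC1 by 1.20 and NDUFB5 by 1.80, while NDUFS3 fell by 0.57. Glycolysis genes rose in 11 of 16 cases and fell in 1, also adjusted over the list alone (median 0.59, and 0.72 with the day as a block; adjusted p = 0.00195, adjusted p = 0.196 with an estimated correlation), with GPI up by 1.96 and ALDOC down by 0.42. Matrix and integrin genes rose in 13 of 26 and fell in 6 by both adjustments, over all genes and adjusted over the list alone (median 0.31, and 0.34 with the day as a block; adjusted p = 0.0409, adjusted p = 0.393 with an estimated correlation), with COL4A5 up by 2.56 and CD44 down by 1.03. Oxidative stress genes rose in 11 of 19 and fell in 4, also adjusted over the list alone (median 0.34, and 0.42 with the day as a block; adjusted p = 0.0405, adjusted p = 0.337 with an estimated correlation). GPX4, which reduces lipid peroxides, rose by 1.45, and catalase, CAT, fell by 0.89. With spike-in scaling the medians were 0.57 for matrix and integrin genes, 0.58 for oxidative stress genes and 0.58 for oxidative phosphorylation. Targets of p53 rose in 9 of 16 and fell in 2, also adjusted over the list alone (median 0.50, and 0.46 with the day as a block; adjusted p = 0.0402, adjusted p = 0.196 with an estimated correlation), with BAX and FAS up by 2.21 and 1.71 and TRIAP1 down by 0.47.

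Mitosis genes fell in 31 of 40 cases and rose in 1 between 0 h and 72 h, also adjusted over the list alone (median -0.55, -0.59 with the day as a block and -0.32 with spike-in scaling; adjusted p = 3.33e-06, adjusted p = 0.196 with an estimated correlation), with BIRC5 down by 1.43 and BUB1 up by 0.31. Immediate early genes fell in 19 of 27 with no rise, also adjusted over the list alone (median -0.60, -0.56 with the day as a block and -0.28 with spike-in scaling; adjusted p = 0.0028, adjusted p = 0.453 with an estimated correlation), among them FOS by 1.51 and SRF by 1.09. NF-kB and cytokine genes fell in 14 of 17 with no rise, also adjusted over the list alone (median -0.46, -0.49 with the day as a block and -0.22 with spike-in scaling; adjusted p = 0.00421, adjusted p = 0.236 with an estimated correlation), NFKB1 by 1.30 and CXCL2 by 1.81. Leukocyte markers fell in 6 of 8 cases and rose in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.235), with CD3E at -0.57 and HLA-DPA1 at 0.55. The other 25 lists were not called. No hybridisation day held both stored and 72 h arrays, so the day as a block compares them only through 24 h arrays, and it left 4389 calls. Scaling to the spike-in controls moved the median log2 change of all probe sets from -0.08 to 0.17 and the share of rises from 44.7% to 76.4%.

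What still differed after 72 h of rehydration was asked against the unstored spheroids. GADD45B was 7.89-fold higher than before storage (40568 ± 354 against 5321 ± 1727, n = 3), and GDF15, a stress-induced cytokine, was 6.83-fold higher (5856 ± 204 against 865 ± 142). TP53I3 was 6.68-fold higher, the kinase genes SGK1 and PLK2 6.52-fold and 5.85-fold, and HEXIM1, an inhibitor of transcription elongation, 5.44-fold. NPTX2, HBEGF, WDR47 and PHLDA2 were 4.33-fold to 4.99-fold higher. INSIG1 was 4.45-fold lower (5604 ± 161 against 25230 ± 4639). SCD was 3.3-fold lower and SQLE, squalene epoxidase, 3.2-fold lower. NRN1, IGFBP5, DHCR7, HILPDA, MSMO1, MYC and FASN, the fatty acid synthase, were 2.51-fold to 3.16-fold lower. In all, 2330 probe sets were higher and 2269 lower, 175 and 62 of them by at least 2-fold (116 and 110 with spike-in scaling).

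Targets of p53 were higher at 72 h than in unstored spheroids, with 13 of 16 rising and none falling (14 and 0 adjusted over the list alone; median log2 change 0.81, adjusted p = 2.29e-10, and adjusted p = 0.000286 with an estimated correlation). PPM1D, a phosphatase that restrains p53 signalling, rose by 1.95 ± 0.09 (SE), GADD45A by 1.38 ± 0.08 and TRIAP1 by 0.80 ± 0.05. Genes of sterol and lipid synthesis were lower. Cholesterol synthesis had 12 of 17 falling and 1 rising (13 and 1 adjusted over the list alone; median -0.81, adjusted p = 3.06e-07, and adjusted p = 0.013 with an estimated correlation), with IDI1 down by 1.26 and PMVK up by 0.30. Fatty acid synthesis had 9 of 11 falling and none rising (10 and 0 adjusted over the list alone; median -0.44, adjusted p = 2.19e-05, and adjusted p = 0.00604 with an estimated correlation), among them ACACA, the acetyl-CoA carboxylase, by 0.69 and MID1IP1 by 0.92. Autophagy and lysosome genes rose in 13 of 29 cases and fell in 1, also adjusted over the list alone (median 0.24, and 0.06 with spike-in scaling; adjusted p = 3.48e-05, and adjusted p = 0.00425 with an estimated correlation). The autophagosome gene MAP1LC3B rose by 1.23, the cargo receptor gene SQSTM1 by 0.84 and ATP6V0D1 by 1.56, while GLA fell by 0.63.

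The remaining calls at 72 h were lost with an estimated correlation. Immediate early genes rose in 17 of 27 cases and fell in 1 (19 and 1 adjusted over the list alone; median 0.57, and 0.36 with spike-in scaling; adjusted p = 1.46e-07, adjusted p = 0.192 with an estimated correlation), with FOS up by log2 1.82 and MYC down by 1.37. Mitosis genes fell in 24 of 40 and rose in 3 (25 and 3 adjusted over the list alone; median -0.34, adjusted p = 1.96e-05, adjusted p = 0.0804 with an estimated correlation), with CENPF down by 0.98 and NEK2 up by 0.94. Glycolysis genes fell in 8 of 16 with no rise (9 and 0 adjusted over the list alone; median -0.31, adjusted p = 0.00017, adjusted p = 0.0701 with an estimated correlation), PFKP by 1.12 and HK1 by 0.57. Hypoxia genes fell in 14 of 26 and rose in 2 (15 and 4 adjusted over the list alone; median -0.41, adjusted p = 0.000577, adjusted p = 0.235 with an estimated correlation), with CA12 down by 1.04 and JMJD6 up by 0.60. Histone genes rose in 7 of 10 with no fall, also adjusted over the list alone (median 0.71, adjusted p = 0.000679, adjusted p = 0.157 with an estimated correlation), H2BC5 by 1.28. All 7 metallothionein genes fell, also adjusted over the list alone (median -0.43, adjusted p = 0.000782, adjusted p = 0.235 with an estimated correlation), MT1X by 0.59. Interferon response genes rose in 6 of 15 and fell in 1 (7 and 1 adjusted over the list alone; median 0.23, and 0.08 with spike-in scaling; adjusted p = 0.0154, adjusted p = 0.23 with an estimated correlation), with IRF7 up by 0.96 and IFITM1 down by 0.33. The other 22 lists were not called. Among them oxidative phosphorylation, lower after storage, had 9 of 58 genes above and 11 below the unstored level (10 and 12 adjusted over the list alone; adjusted p = 0.917). The 28S 3' ribosomal RNA control read 5469 ± 795 at 72 h and 2420 ± 241 in unstored spheroids, and the other 28S 3' control 2221 ± 386 and 2389 ± 235. Spheroid and 72 h arrays shared no hybridisation day. Rises were 50.7% of the calls, against 62.2% with median centring, 60.7% as deposited and 27.8% with spike-in scaling, which moved the median log2 change of all probe sets from -0.03 to -0.19. Of the 40 list calls over all comparisons, 6 held with an estimated correlation.

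**Figure D3:**
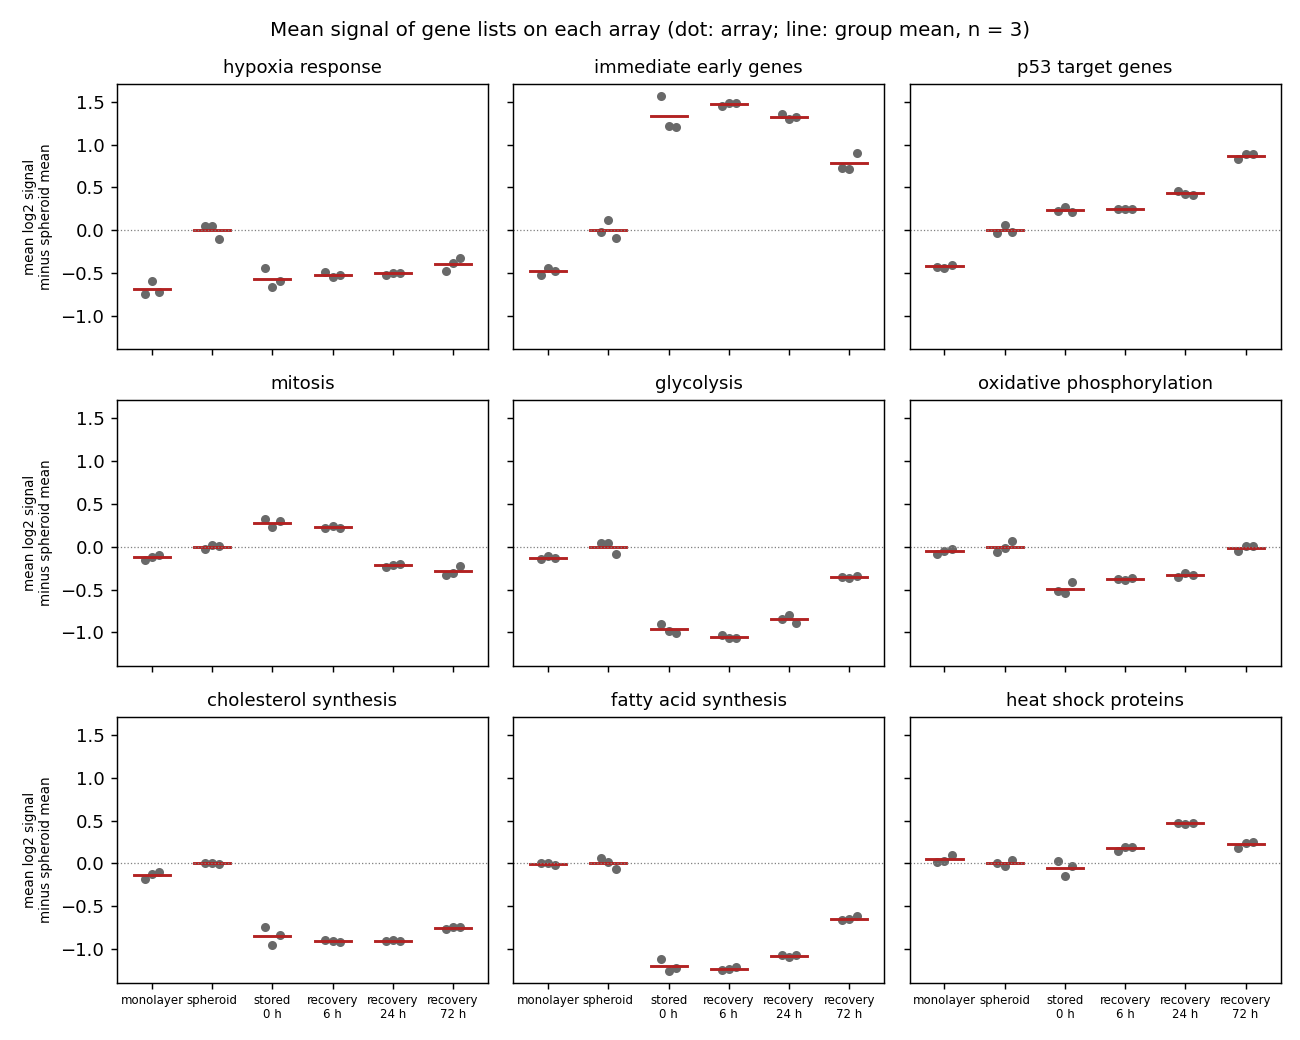
Mean log2 signal of 9 gene lists on each array, minus the spheroid mean (y axis, log2 units), by group (x axis); dots are arrays and lines are group means, n = 3. Targets of p53 lay at 0.23 at 0 h and 0.87 at 72 h (in spike-in scaling their median at 0 h was -0.20), and cholesterol synthesis at -0.84 and -0.75.

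Of the 9260 probe sets called in stored 0 h against spheroid, 3292 (35.55%) also differed from unstored spheroids at 72 h in the same direction. These were 1668 of the 4926 that had risen (33.86%) and 1624 of the 4334 that had fallen (37.47%). Another 485 differed in the opposite direction and 5483 were not called. The median log2 change of the probe sets that had risen was 0.53 at 0 h and 0.10 at 72 h. For those that had fallen it was -0.73 and -0.17. Between 0 h and 72 h, 7641 of the 9260 moved back by a called change. That count rests on the same stored arrays that chose the 9260. Part of it can therefore come from the spread or the hybridisation day of those arrays. The comparisons of stored 0 h and of 72 h with spheroids used the same spheroid arrays. Independent lists of these sizes would share 1677 probe sets, which leaves out the shared controls. In 20 simulations of unchanged groups at most 4 and 3 probe sets were called, so the simulated overlap of 0 sets no scale for lists of this size. The correlation of the log2 changes across probe sets was 0.58, against a simulated mean of 0.50, their covariance was 0.173 against 0.00552, and 62.4% had the same sign against 66.7%. The 3 spheroid arrays were too few to split into separate controls of at least 2 each, so part of the overlap can come from the shared controls. Spheroid arrays shared no hybridisation day with stored or 72 h arrays, and the 72 h cells had been back in medium. Neither difference can therefore be assigned to storage alone.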

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

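The scaling test for the breadth of storage, its check of 24 h arrays against monolayers, the day block for the p53 targets and the session block at 6 h were chosen only after the results were seen.

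Part of the 12 control probe sets for ribosomal RNA, which no comparison used, read higher after storage or rehydration than in unstored spheroids. A signal of at least 2-fold the spheroid level in these unused data was what drew attention to them. At 6 h the 18S control was higher at its 3' end by 2.19-fold, at its 5' end by 2.15-fold and in its middle by 2.89-fold. The 28S control at its 3' end was 2.03-fold higher at 0 h, 3.93-fold at 6 h and 2.25-fold at 72 h, and in its middle 2.23-fold at 6 h. Among the array's other controls for the same RNAs, 18S was 2.05-fold higher at its 5' end and 2.5-fold in its middle at 6 h, and 28S at its 5' end 2.14-fold at 0 h and 2.32-fold at 6 h. The other 28S 3' control differed from this, at 1.25-fold, 1.1-fold, 0.993-fold and 0.924-fold the spheroid level at 0, 6, 24 and 72 h. With spike-in scaling the 28S 3' control stayed above the spheroids at these times, by log2 0.59, 1.65 and 1.01, while the 72 h value of the 18S 3' control went from 0.11 to -0.07 and the 6 h value of the other 28S 3' control from 0.14 to -0.34. The cause was not tested.

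Stored spheroids differed from unstored ones at 9260 probe sets, and array handling was weighed as the whole cause of this difference. Against the day of the spheroid arrays, 80.3% of these probe sets were called in the same direction against the monolayers of another day (7439, with 118 opposite). The stored arrays are shared there, and the share lay just over the bound of 80% that had been set. For scaling, the count at 2-fold was 2461 with median centring, 2461 as deposited and 3017 with spike-in scaling, beside 2490. The bound concerned only the total, and spike-in scaling gave 450 rises and 2567 falls, beside 1066 and 1424. The number of changes thus held under the other scalings, but the balance of rises and falls did not. For the day of the stored arrays, day 3, the test did not decide. In 24 h arrays of other days 63.2% were called in the same direction against the same spheroid arrays (5856, with 246 opposite). Only 56.1% were against the monolayers, which share no array (5193, with 588 opposite), short of the bound set. On the principal component with 70.6% of the variance, however, the 24 h arrays of days 4 and 5 lay at 20 and 19.6. The 24 h array of day 3 lay at 19, and the spheroids between -44.6 and -44.1. These positions argue against day 3 as the whole cause, while a part played by it stays open. RNA breakdown during storage may also contribute, since the GAPDH and ACTB controls for it lay at the ceiling, and a response of the cells to drying stays a hypothesis beside these. Of the 10 splits of the 6 arrays, the real one gave the 9260 and the highest other gave 1, and 10 splits are too few for a share under 0.05. The other splits also mix both groups on each side, which widens the spread, so their low counts set no scale for chance.

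Targets of p53 were higher at 72 h than in unstored spheroids, by a median log2 of 0.81. The day of the spheroid arrays was tested against the monolayers, where the median was 1.181 and all 16 members rose. The monolayers differ from the spheroids in culture form as well as day. The list was already higher in spheroids than in monolayers, by a median of 0.39. This test therefore cannot decide on the day of the spheroid arrays. The day of the 72 h arrays was tested with a day block against stored 0 h, where the median was 0.456. Scaling left the median against spheroids at 0.692 or above. As a hypothesis, the list may rise in rehydrated cells as a stress response, although HEK293 cells carry adenoviral proteins that act on p53, and 11 of the 14 members in no other list rose. Whether p53 itself drives these genes was not tested.

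The 6 h comparison gave 1189 probe sets, and the hybridisation session of part of the stored arrays cannot be told apart from it. The stored array run in the session of the 6 h arrays lay 0.316 of the way from the other stored arrays to the 6 h arrays, between the bounds set for the session as cause and as no cause. With the session as a block over all arrays 200 probe sets were called: for the 1189 the median absolute log2 change went from 0.40 to 0.33, the median standard error from 0.091 to 0.124 and the residual degrees of freedom from 12 to 8, and 1188 had the same sign. The arrays of the stored arrays' day alone gave 179 without the block, with 4 degrees of freedom, and 14 with it, with 3. Among the 10 splits of the 6 arrays, too few for a share under 0.05, the highest other gave 347 probe sets, and it followed the session but for 1 array.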

How the results depend on the processing

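The session blocks, spike-in scaling, values as deposited and the fit without ceiling probe sets were chosen only after the data were seen. None of the 100 gene results with the largest changes reversed its direction in the settings that held its probe set. They had been picked for large changes without overlap between arrays, so a reversal was unlikely from the start. Of 1884 calls of list members, run under the scalings only, the sign changed in 3 with median centring, 0 as deposited and 103 with spike-in scaling, 71 of these for stored against spheroid. EBP, ACSL1 and LAPTM5 kept their sign there but lost their calls with spike-in scaling, at 0.09, 0.08 and 0.02. The balance of rises and falls also turned in some comparisons. Stored against spheroid went from 4926 rising and 4334 falling to 4365 and 4469 with median centring, 4413 and 4445 as deposited and 1664 and 6348 with spike-in scaling. At 24 h against stored it went from 3034 and 3375 to 3297 and 2199, 3225 and 2507, and 2822 and 682 under these scalings, 1980 and 1855 with a stricter filter and 1899 and 1407 with the day block, and turned by small margins without stored replicate 1 (2881 and 2870), stored replicate 2 (2726 and 2666) or 24 h replicate 3 (2658 and 2481). At 72 h against stored it went from 4151 and 5130 to 4610 and 4230, 4531 and 4439, and 4804 and 1485 under the scalings, 2663 and 2647 with a stricter filter and 2388 and 2001 with the day block. For 72 h against spheroid, 2330 and 2269 went to 859 and 2232 with spike-in scaling, 3080 and 3390 with array weights, 2977 and 3242 with the day as a random block and 2205 and 2229 without 72 h replicate 1. For spheroids against monolayer, 2118 and 2085 went to 2372 and 2449 with array weights and 2807 and 2980 with the day as a random block. At 2-fold or more the balance also turned for stored against spheroid (1066 and 1424) and at 24 and 72 h against stored (460 and 46, 1154 and 500). The total counts lay within 1.5 times the main value except as follows. Asking for at least 2-fold gave 126 probe sets in spheroids against monolayer, 2490 in stored against spheroid, 50, 506 and 1654 at 6, 24 and 72 h against stored, and 237 at 72 h against spheroid, by construction. A stricter filter tested fewer probe sets and gave 5522 for stored against spheroid, 3835 and 5310 at 24 and 72 h against stored, and 6696 for any difference among the groups. Spike-in scaling gave 1861 for spheroids against monolayer and 346 and 3504 at 6 and 24 h against stored, and the cause was not tested. The compared arrays alone gave 180 at 6 h, with fewer arrays for the spread. The session block gave 200 at 6 h over all arrays and 14 over the arrays of the day, with fewer degrees of freedom, and the day block gave 3306 and 4389 at 24 and 72 h, where it left fewer arrays to compare within a day. Median centring put the GAPDH ratio at 0.01 beside 0.002, at the ceiling. Leave-one-out fits gave 3113 to 3748 for spheroids against monolayer and 8675 to 9231 for stored against spheroid. They gave 5139 to 6604 and 8491 to 9171 at 24 and 72 h, and 3590 to 4434 for 72 h against spheroid. For any difference they gave 11071 to 11614, and 2722 to 3422 for probe sets called after storage that still differed at 72 h. At 6 h they ran from 598 without 6 h replicate 3 to 2305 without stored replicate 3, with 695 without stored replicate 2 and 755 without 6 h replicate 2. The GAPDH ratio ran from 0.001 to 0.003 and the ACTB ratio from -0.061 to 0.015. With the replicate number as a block the counts were 4411, 9349, 1415, 6627, 9348 and 4783 in the order of the report. Residuals of equal numbers correlated with a median r of 0.076 (-0.216 to 0.37), and those of other numbers with -0.04 (-0.44 to 0.497). Of 45 pairs of equal numbers 20 lay above 0.1, and of 90 other pairs 18. Of the 18 arrays 9 correlated best with their own number. The numbers were not taken as pairs in the main model, although some pairing cannot be excluded. Of the 100 results only ones of the 6 h comparison lost a call: 7 with spike-in scaling, 1 with median centring, 1 as deposited, 2 without a filter, 8 with the compared arrays alone, 1 with the day block, 16 and 10 with the session block over the day and over all arrays, and 14, beside 586 that kept it, over the leave-one-out fits. Of 396 counts of list members, 359 stayed within 1.5 times with another choice of probe set and 327 with median centring. Signals near the background of the arrays limit small folds among dim probe sets.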

Other observations

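All gene family tests in this part were chosen only after the result was seen, while the splits of the arrays were planned.

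Zinc finger genes rose more often on storage than measured genes at large. This family and the splicing family below were picked from these same data, so their p-values are no independent test. Of 146 genes named ZNF, 88 rose and 23 fell, so 60.3% rose where 38.1% of all measured genes did (median log2 change 0.41, but -0.03 with spike-in scaling, where it lay 0.32 above that of all genes). ZNF34 rose by log2 3.90, ZNF211 by 2.06 and ZNF274 by 1.91 (camera adjusted p = 1.29e-05, and adjusted p = 0.00625 with an estimated correlation). At 72 h 66 of them were above and 7 below the unstored level. RNA binding and splicing genes named RBM, SRSF or CLK showed 23 rising and 5 falling of 35 on storage (median 0.35, but -0.02 with spike-in scaling; adjusted p = 0.0226 with an estimated correlation), with CLK1 at 2.90, RBM39 at 1.92 and SRSF10 at 1.38. As a hypothesis, transcripts of these families may have been kept better than the average transcript in dry cells, which no further test addressed.

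Other families gave no call with an estimated correlation. Of 49 mitochondrial ribosomal protein genes 14 rose and 25 fell on storage (adjusted p = 0.486), and of 68 genes named TMEM 18 rose and 38 fell (adjusted p = 0.392). Of 14 cytosolic aminoacyl-tRNA synthetase genes with symbols ending in ARS1, 3 rose and 3 fell in spheroids against monolayer (camera adjusted p = 0.961), although VARS1 fell 2.08-fold. The set is incomplete: FARSA, which fell 2.18-fold, was left out by its symbol.

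Regrouping the arrays asked whether chance grouped them. Of 100 regroupings of the 18 arrays, only the real one, 1 of 100, gave as many as 11528 probe sets with any difference. The highest other gave 3409. A random assignment of arrays to groups is thus unlikely to give such a count. Arrays of a group largely shared a hybridisation day, however, so the day would set the real grouping apart as well. For comparisons of 3 against 3 arrays 10 splits are too few for a share under 0.05. The other splits also put arrays of both groups on each side, which widens the spread. Low counts there are largely built in and set no scale for chance. In each of these comparisons the real split was the 1 with as many probe sets: 4203 against 1 in the highest other for spheroids and monolayer, 6409 against 0 at 24 h, 9281 against 3 at 72 h, and 4599 against 0 for 72 h and spheroid.

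Some genes had probe sets called in opposite directions. Among genes with several called probe sets these were 71 of 565 in spheroids against monolayer, 174 of 1542 in stored against spheroid, 2 of 107, 136 of 920 and 230 of 1532 at 6, 24 and 72 h against stored, and 23 of 647 in 72 h against spheroid. None of the named genes was among them.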
